A study of Homo sapiens with 6 samples.

How the data were processed

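Expression was measured in human peripheral blood monocytes 48 h after infection with human cytomegalovirus (HCMV, strain Towne/E) or mock infection. HCMV is a herpesvirus that enters blood monocytes, and LY294002 is an inhibitor of phosphatidylinositol 3-kinases (PI(3)K), a family of lipid kinases that signal through AKT. The 6 arrays fell into 3 groups of 2: mock-infected cells, HCMV-infected cells, and cells pretreated with LY294002 and then infected. Per the labels, the cells were infected at a multiplicity of infection of 15, cultured in medium with 10% human serum, and 10 µg of total RNA was labelled with biotin for each Affymetrix array. The labels give neither the concentration of LY294002 nor its time on the cells, and no group received the inhibitor without virus.

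The deposited values are intensities, 1 MAS5 signal per probe set and array on a linear scale, per the submitters' processing notes. MAS5 summarises the matched and mismatched probes of a probe set into a background-adjusted signal. Its version is not given in the sources used here. The deposited signals had already been brought to a common level by the authors, since the 2% trimmed means of the 6 arrays all lay between 2501.2 and 2501.4. MAS5 signals near the background are imprecise, which widens the spread of dim probe sets, and detection calls were not used here.

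The signals were rescaled to the same 2% trimmed mean, 32 was added, and log2 was taken. A fold change is therefore on the log2(signal + 32) scale, which understates the change of dim genes. Of the 12625 probe sets, 67 controls stayed in the scaling and out of the tests. Among the other 12558 probe sets, those with a mean log2 value at or above the 40th percentile were kept, which is a mean log2 value of 9.1, or a signal of about 517.1. This left 7538 probe sets. Gene names came from the platform's annotation table, in which 10961 probe sets had 1 gene symbol, 545 had several and 1119 had none. Of the first kind, 10949 were matched through their Entrez numbers to a current gene table, and 0 symbols changed. No name was taken from a probe set with several symbols. The value of a gene with several probe sets was that of the probe set with the highest mean, which gave 8226 genes measured and 5424 tested. No genome build was used, so no coordinates are given.

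Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on all 6 arrays, which shared 1 estimate of the spread. This left 3 residual degrees of freedom, to which the prior added a median of 4.34. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, with a threshold of 0.05. The ± values beside log2 differences are standard errors, and those beside group means are standard deviations with n = 2. The labels call the replicates biological but name no donors or cultures, so p-values measure only the spread between these samples, which may be partly technical. The number of arrays limits the precision of every value.

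Gene lists were tested with camera in limma, on 1 probe set per gene, with the preset correlation between genes of 0.01, and adjusted over the 30 lists within a comparison. Camera compares the members of a list with all other genes. The lists covered interferon and cytokine responses, macrophage states, cell death, adhesion, metabolism, stress, signalling and markers of other blood and stromal cells. Some genes belong to more than 1 list, so list calls are not all separate results. The M1-associated list shares genes such as IL6 with the cytokine list and OASL with the interferon list. The maturation list shares genes such as CTSD with the matrix list. Each test was repeated with an estimated correlation and with fry, whose directional p asks whether the members move one way on balance and whose mixed p asks whether they change in either direction. Member counts are given over all probe sets tested and adjusted over the list alone.

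The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, up to 10 genes with the largest rise and up to 10 with the largest fall among those past the threshold without overlap between groups. It added up to 4 members of each list with the smallest p, and the fixed genes MCL1, IL1B, IL6, TNF, CXCL10, CCL2, ICAM1, MRC1, CD163 and BCL2A1. Genes named outside the rule are said to be so. Where values without overlap are counted, chance alone gives 16.7% in each direction for a single gene with 2 arrays against 2. Genes of a list move together, so a list can separate as a whole, and these counts are no test. Lists that camera did not call also passed this share, so a count above 16.7% does not by itself mark a shifted list.

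The share of the infection effect kept under LY294002 was measured on separate arrays: probe sets that differed at least 2-fold between the HCMV and mock arrays of 1 replicate number were chosen, and their mean change was taken from the arrays of the other number. Simulated groups that share an array group, with no infection or LY effect, gave overlaps and correlations between comparisons where nothing changes (100 simulations).

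The steps were tested on simulated data for the comparison of HCMV with mock, with 200 of 7538 probe sets changed in each of 20 simulations and errors drawn independently for each probe set. At a 2-fold change 1.5% of the changed probe sets were recovered, at 4-fold 35.7%, at 16-fold 92.7% and at 64-fold 97.2%, with 8.4 false calls per simulation. Lists shifted by 1 log2 unit were called in 96% of cases and unshifted lists in 0.318%, over 5424 genes. These rates need not hold for the data. The 200 changed probe sets ease the adjusted threshold compared with the 4 called in HCMV against mock. There FABP4 differed 128-fold without passing (limma, adjusted p = 0.115). Independent errors also leave out the correlation within lists, and camera called 14 of 30 lists between replicates 1 and 2.

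The alternatives were quantile normalization, the values as deposited, an offset of 1 or 128, no filter or a filter at the 60th percentile, no intensity trend, only the groups compared, the replicate number as a block, a minimum of 1.5-fold, 1 probe set per gene, and leaving out each array in turn. Where leaving out an array left a group with 1 array, that array was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9.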

Results

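Transcript levels were compared in 6 samples of human blood monocytes, 48 h after mock infection, HCMV infection, or HCMV infection after pretreatment with the PI(3)K inhibitor LY294002 (LY), with 2 arrays per group. The comparisons ask how monocytes respond to the virus and which levels in infected cells change with LY. The median signal per array ranged from 649.9 to 1138. Arrays of 1 group differed by a median of 1.32-fold in mock, 1.45-fold in HCMV and 1.5-fold in LY-pretreated cells. Across genes, which are not independent replicates, the log2 values of the 2 arrays of a group correlated with r = 0.899 in mock, 0.844 in HCMV and 0.791 in LY-pretreated cells. HCMV replicate 2 lay closer to mock replicate 1 (r = 0.892) than to the other HCMV array. LY-pretreated replicate 2 lay closer to mock replicate 1 (r = 0.883), HCMV replicate 2 (r = 0.869) and mock replicate 2 (r = 0.837) than to the other LY-pretreated array.

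HCMV infection was followed by a rise of inflammatory chemokines, a cytokine and an interferon-inducible gene. Among 7538 probe sets, 4 rose and 0 fell in HCMV against mock (limma, adjusted p under 0.05), while 694 had an unadjusted p under 0.05, of which 385 were lower. IL6, which encodes a pro-inflammatory cytokine, rose 223-fold (log2 7.8 ± 0.76, adjusted p = 0.0255), from a mean log2 signal of 7.43 ± 1.17 to 15.23 ± 1.41. The genes CCL7 and CCL8, which encode chemokines that attract monocytes, rose 121-fold (log2 6.92 ± 0.48, adjusted p = 0.00856) and 80.1-fold (log2 6.32 ± 0.59, adjusted p = 0.0255). The interferon-inducible gene IFI27 rose 58.1-fold (log2 5.86 ± 0.58, adjusted p = 0.0255), and for all 4 genes both infected arrays lay above both mock arrays. The call of each of these 4 genes was lost without mock replicate 1 (adjusted p = 0.084 to 0.15) and without mock replicate 2 (adjusted p = 0.13 to 0.28), and those of CCL8, IL6 and IFI27 also without HCMV replicate 1 (adjusted p = 0.23, 0.17 and 0.47). Over all alternatives the adjusted p ranged from 0.0023 to 0.13 for CCL7, 0.0041 to 0.23 for CCL8, 0.011 to 0.17 for IL6 and 0.01 to 0.47 for IFI27. Their log2 differences stayed within 6.29 to 7.56, 5.52 to 7.13, 6.81 to 8.8 and 5.18 to 6.54. The count was 0 without either mock array (538 and 271 with an unadjusted p under 0.05), 1 without HCMV replicate 1, 13 without HCMV replicate 2, 9 without either LY-pretreated array, 1 without the intensity trend and 9 with only the groups compared.

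Interferon-stimulated and inflammatory genes had medians above 0 after infection. Of 39 interferon-stimulated genes tested, 1 rose over all genes and 22 rose adjusted over the list alone. Without overlap 36 lay higher, where chance gives 16.7% for a single gene. The genes of this list moved together (estimated correlation 0.743), so they are not independent counts. The list had a median log2 difference of 1.99 (camera, adjusted p = 1.2e-27, and adjusted p = 0.54 with an estimated correlation). Examples below the threshold were IFIT2, an inhibitor of viral translation (log2 5.26 ± 0.86, adjusted p = 0.147), OASL (log2 4.26 ± 0.76, adjusted p = 0.207) and the antiviral enzyme RSAD2 (log2 5.91 ± 1.26, adjusted p = 0.289). Of 31 inflammatory cytokines and NF-kB targets, 3 rose over all genes and 14 adjusted over the list alone, and 24 lay higher and 1 lower without overlap, with a median of 2.09 (adjusted p = 4.7e-26, and adjusted p = 0.54 with an estimated correlation). That median was 3.14 without HCMV replicate 2. IL1B, a fever-inducing cytokine, differed by log2 4.48 ± 0.65 (adjusted p = 0.114), the chemokine gene CCL4 by 3.51 ± 0.50 (adjusted p = 0.114) and TNF by 3.1 ± 0.72 (adjusted p = 0.333). Of 29 M1-associated macrophage genes, 1 rose and 7 did so adjusted over the list alone (median 1.59, adjusted p = 3.4e-15, and adjusted p = 0.54 with an estimated correlation). The 1 that rose was IL6, which also belongs to the cytokine list. CXCL10, a chemokine induced by interferons, differed by log2 6.91 ± 2.85 (adjusted p = 0.521) and CCL2 by 2.91 ± 1.36 (adjusted p = 0.57). NK cell markers differed between the infected arrays, where the list mean lay at 1.94 on HCMV replicate 1 and at −1.44 on HCMV replicate 2, relative to the mean of the 6 arrays.

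Cell death genes had medians above 0 after infection. Of 16 anti-apoptotic genes, 0 passed over all genes in limma (3 higher and 1 lower at an unadjusted p under 0.05) and 1 adjusted over the list alone, with a median of 0.51 (camera, adjusted p = 0.0018, and adjusted p = 0.54 with an estimated correlation). That median was 0.26 without HCMV replicate 1. CFLAR, an inhibitor of death receptor signalling, differed by log2 1.85 ± 0.39 (adjusted p = 0.282), BCL2A1, a survival gene of the BCL2 family, by 2.36 ± 0.81 (adjusted p = 0.443) and DAD1 by −1.37 ± 0.52 (adjusted p = 0.486). For MCL1, a survival gene of the same family, the difference was 0.64 (95% interval −0.27 to 1.55, adjusted p = 0.648). Of 24 pro-apoptotic genes 0 passed (3 at an unadjusted p under 0.05), with a median of 0.21 (adjusted p = 0.027, and adjusted p = 0.65 with an estimated correlation). TNFSF10, a death receptor ligand that interferon induces, differed by 3.32 ± 1.08 (adjusted p = 0.414), FAS by 1.76 ± 0.65 and the caspase gene CASP1 by 1.23 ± 0.46 (both adjusted p = 0.479). The pro-apoptotic call was lost without mock replicate 2 (median 0.165, adjusted p = 0.18) and without HCMV replicate 1 (median 0.09, adjusted p = 0.25), and the median was 0.33 without HCMV replicate 2. Whether the 2 lists shifted differently was not tested.

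Macrophage maturation genes had a median below 0 after infection, and classical monocyte genes were low on HCMV replicate 1. Of 32 macrophage maturation genes, 0 passed over all genes (1 higher and 7 lower at an unadjusted p under 0.05). Adjusted over the list alone, 5 were lower and 1 higher. Without overlap 17 lay lower and 2 higher, where chance gives 16.7% for a single gene. Lists that camera did not call separated too. Of 34 oxidative phosphorylation genes 13 lay lower and 6 higher, and of 25 PI3K pathway genes 10 lower and 5 higher. The maturation median was −0.54 (camera, adjusted p = 0.0059, and adjusted p = 0.54 with an estimated correlation). The fatty acid carrier gene FABP4 differed by log2 −7 ± 1.05 (adjusted p = 0.115), from 14.2 ± 1.17 in mock to 7.2 ± 0.90 in HCMV. The differences were −3.74 ± 0.91 for GPNMB, a membrane glycoprotein gene (adjusted p = 0.341), and −3.96 ± 1.01 for the lipid carrier gene APOE (adjusted p = 0.347). Of 16 classical monocyte genes 0 passed (5 lower at an unadjusted p under 0.05), 1 was lower adjusted over the list alone and 6 lay lower without overlap, with a median of −1.46 (adjusted p = 0.019, and adjusted p = 0.69 with an estimated correlation). The chemokine receptor gene CX3CR1 differed by −2.32 ± 0.44 (adjusted p = 0.219), CSF3R by −2.82 ± 0.76 (adjusted p = 0.347) and the lysozyme gene LYZ by −1.83 ± 0.62 (adjusted p = 0.442). Of the 16 genes, 2 read higher on HCMV replicate 1 than on replicate 2, among them CX3CR1 (9.557 against 8.743). Named outside the rule, CD14 and FCN1 of this list read 12.57 and 10.06 on HCMV replicate 1 and 16.88 and 15.76 on replicate 2. In mock they read 16.31 and 16.31 on replicate 1 and 16.38 and 15.86 on replicate 2. The monocyte list mean lay at −1.27 on HCMV replicate 1, on which 18S ribosomal RNA control probe sets read 29940, and at 0.70 on HCMV replicate 2, on which they read 110.6, against 1.03 and 0.88 in mock. Without HCMV replicate 1 the calls of both lists were lost (maturation median −0.445, adjusted p = 0.1, monocyte median −0.08, adjusted p = 0.68). The monocyte call was also lost without mock replicate 1 (adjusted p = 0.1), and the maturation median was −0.93 without HCMV replicate 2. The 30 M2-associated genes had a median of −0.85 and were not called by camera (adjusted p = 0.16), with list means of −0.67 on HCMV replicate 1 and 0.61 on HCMV replicate 2 against 0.68 and 0.77 in mock, and a median of −0.12 without HCMV replicate 1.

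Camera also called T cell markers downwards in the infected cells. Of 14 T cell markers 0 passed (5 lower at an unadjusted p under 0.05) and 4 were lower adjusted over the list alone, with a median of −1.17 (camera, adjusted p = 2.1e-05, and adjusted p = 0.65 with an estimated correlation). CD3E, a subunit of the T cell receptor complex, differed by −1.74 ± 0.50 (adjusted p = 0.364) and the T cell kinase gene LCK by −1.83 ± 0.51 (adjusted p = 0.348). The median was −0.48 without HCMV replicate 2, −0.68 without mock replicate 2, −1.76 without mock replicate 1 and −1.99 without HCMV replicate 1. Ribosomal protein genes had a median of −0.615 over 26 genes (adjusted p = 0.00029, and adjusted p = 0.69 with an estimated correlation), a call that was lost without mock replicate 2 (median −0.29, adjusted p = 0.21) or HCMV replicate 2 (median −0.35, adjusted p = 0.13), with a median of −0.98 without mock replicate 1. The median of all probe sets tested was itself −0.18, and −0.05 after quantile normalization, and camera reads each list relative to the other genes.

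Smaller upward list shifts were also called by camera. Pattern recognition and interferon pathway genes had a median of 0.5 (adjusted p = 0.0067) and heat shock genes 0.43 (adjusted p = 0.013), each with adjusted p = 0.54 with an estimated correlation. Cell cycle genes had a median of 0.40 (adjusted p = 0.0035, and adjusted p = 0.69 with an estimated correlation), with PCNA, a replication clamp gene, at log2 1.69 ± 0.55 (adjusted p = 0.414) and TYMS at 2.64 ± 1.02 (adjusted p = 0.489). The pattern recognition call was lost without mock replicate 2 (median 0.08, adjusted p = 0.18) and HCMV replicate 2 (median 0.32, adjusted p = 0.23). The heat shock call was lost without mock replicate 2 (adjusted p = 0.17) and HCMV replicate 1 (median 0.175, adjusted p = 0.058). The cell cycle call was lost without mock replicate 1 (median 0.20, adjusted p = 0.076), and without HCMV replicate 1 its median turned to −0.20 (adjusted p = 0.68), and was 1.1 without HCMV replicate 2. In all, camera called 12 of 30 lists, 8 upwards and 4 downwards, while 0 passed with an estimated correlation and 0 in fry (lowest adjusted p = 0.2).

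**Figure D1:**
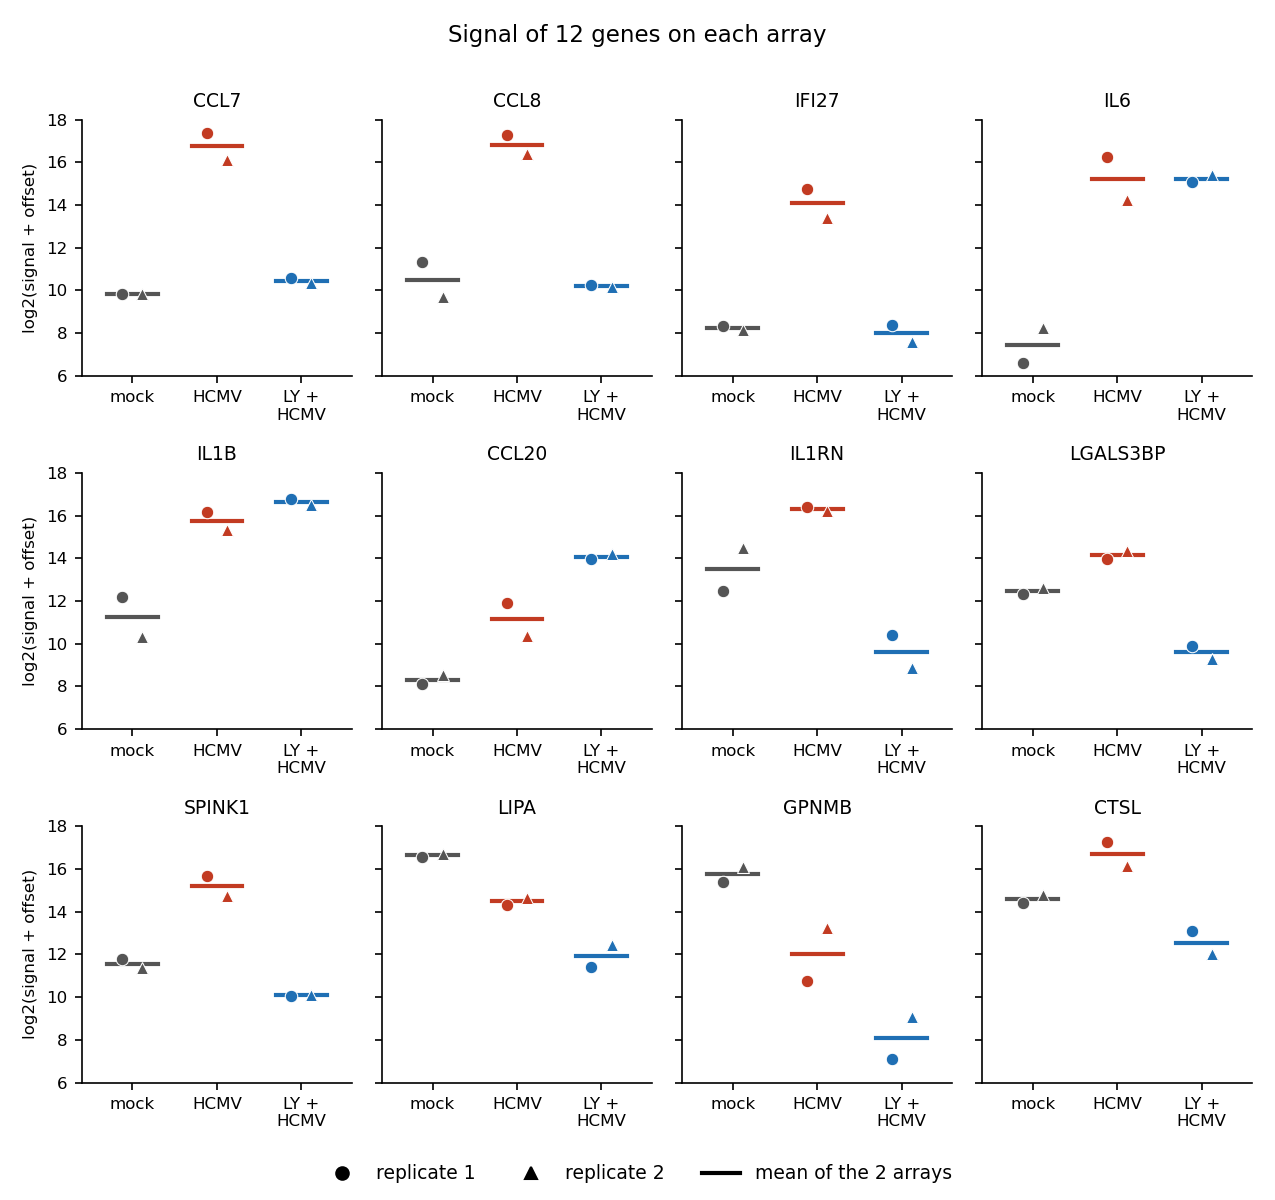
Log2 signal (vertical axis, log2 of signal plus offset) of 12 genes on each of the 6 arrays, in mock-infected, HCMV-infected and LY-pretreated HCMV-infected monocytes, with circles for replicate 1, triangles for replicate 2 and bars for the mean of the 2 arrays. CCL7 means lay at 9.83 in mock, 16.75 in HCMV and 10.45 under LY, while IL6 lay at 15.23 in HCMV and 15.22 under LY.

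Pretreatment with the PI(3)K inhibitor was compared with infection alone to ask which levels in infected cells LY changes. No cells received LY without virus, so a fall under LY may not be the loss of an infection change. Under LY, 0 probe sets rose and 9 fell (limma, adjusted p under 0.05), while 714 had an unadjusted p under 0.05, of which 401 were higher. IL1RN, the natural antagonist of IL1B at its receptor, fell 101-fold (log2 −6.66 ± 0.74, adjusted p = 0.0278), from 16.3 ± 0.11 to 9.63 ± 1.07. CCL8 fell 99.3-fold (log2 −6.63 ± 0.59, adjusted p = 0.0121), CCL7 78.8-fold (log2 −6.3 ± 0.48, adjusted p = 0.0121) and IFI27 68.2-fold (log2 −6.09 ± 0.58, adjusted p = 0.0156). The trypsin inhibitor gene SPINK1 fell 34.5-fold (log2 −5.11 ± 0.43, adjusted p = 0.0121), LGALS3BP, which encodes a secreted galectin-binding protein, 23.5-fold (log2 −4.56 ± 0.40, adjusted p = 0.0121) and LHFPL2 22.4-fold (log2 −4.48 ± 0.45, adjusted p = 0.0184). Each of these 7 genes lay lower on both LY-pretreated arrays than on both HCMV arrays. Against mock, the log2 differences under LY were −3.86 for IL1RN, −3.47 for LHFPL2, −2.87 for LGALS3BP and −1.47 for SPINK1. They were 0.62 for CCL7, −0.31 for CCL8 and −0.23 for IFI27, and none of these passed. The other called probe sets were 1 without a gene symbol (11.6-fold lower, log2 −3.54, adjusted p = 0.0278) and 1 of the stress transcription factor gene DDIT3 (log2 −4.52, adjusted p = 0.0278). The brighter probe set of DDIT3 gave −2.51 ± 0.54 (adjusted p = 0.23).

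Leaving out arrays changed these calls. Without LY-pretreated replicate 2 the count was 3 and 0 of the 9 calls were kept, with adjusted p from 0.064 for CCL7 to 0.099 for IL1RN and the DDIT3 probe set. Without HCMV replicate 1 the count was 3, 1 call was kept, and CCL8 (adjusted p = 0.071), SPINK1 (0.053), LGALS3BP (0.062), LHFPL2 (0.09), IFI27 (0.13) and IL1RN (0.11) were lost. The count was 6 without HCMV replicate 2, where LGALS3BP (adjusted p = 0.07), LHFPL2 (0.076), IFI27 (0.066) and IL1RN (0.13) were lost, and 18 without LY-pretreated replicate 1. The call of the DDIT3 probe set passed only without HCMV replicate 2 among these refits (adjusted p = 0.032), with 0.1 and 0.097 without mock replicates 1 and 2. The probe set without a symbol passed in none of the 6 refits (adjusted p = 0.085 to 0.14). Over all alternatives the adjusted p ranged from 0.0031 to 0.064 for CCL7, 0.0031 to 0.071 for CCL8, 0.0045 to 0.13 for IFI27 and 0.013 to 0.13 for IL1RN. It ranged from 0.0046 to 0.07 for LGALS3BP, 0.0045 to 0.068 for SPINK1 and 0.0045 to 0.09 for LHFPL2. The log2 differences of these 7 genes stayed between −7.42 (IL1RN) and −4.21 (LHFPL2). With no filter the count was 17.

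Interferon-stimulated genes had a median below 0 under LY against infection alone. Of 39 tested, 2 fell over all genes, IFI27 and LGALS3BP, and 22 fell adjusted over the list alone. Without overlap 29 lay lower, where chance gives 16.7% for a single gene. The median was −2.26 (camera, adjusted p = 3.8e-30, and adjusted p = 0.62 with an estimated correlation). OASL differed by log2 −5.21 ± 0.76 (adjusted p = 0.0857) and IFITM3, which restricts virus entry, by −4.09 ± 0.63 (adjusted p = 0.105). The LY-pretreated arrays stood apart on this list, with means of 0.45 on replicate 1 and −2.17 on replicate 2, and the median was −3.36 without replicate 1 and −1.18 without replicate 2. CXCL10 had a log2 signal of 11.14 ± 7.18 under LY against 14.58 ± 2.18 in HCMV (adjusted p = 0.655).

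Of 31 inflammatory cytokines and NF-kB targets tested under LY, 2 fell over all genes, CCL7 and CCL8, while 3 fell and 1 rose adjusted over the list alone. The list median was −0.01 (camera, adjusted p = 0.03, and adjusted p = 0.73 with an estimated correlation), and it turned to 0.38 without HCMV replicate 1 (adjusted p = 0.55) and to 0.16 without LY-pretreated replicate 2 (adjusted p = 0.27), and was −0.38 without HCMV replicate 2 and −0.08 without LY-pretreated replicate 1. IL6 differed by log2 −0.0076 (95% interval −1.79 to 1.77), which does not exclude a level up to 3.42-fold higher, and by 0.12 after quantile normalization. IL1B differed by 0.89 (95% interval −0.64 to 2.41, adjusted p = 0.615), TNF by −1.03 ± 0.72 (adjusted p = 0.595) and CCL20, a chemokine that attracts cells bearing CCR6, by 2.94 ± 0.54 (adjusted p = 0.195). CCL2 differed by −5.52 ± 1.36 (adjusted p = 0.322). M1-associated genes had a median of −0.70 over 29 genes (adjusted p = 0.0037, and adjusted p = 0.73 with an estimated correlation). It turned to 0.155 without HCMV replicate 1 (adjusted p = 0.38) and 0.28 without LY-pretreated replicate 2 (adjusted p = 0.98), and was −1.07 without HCMV replicate 2 and −1.2 without LY-pretreated replicate 1.

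Macrophage maturation and matrix genes had medians below 0 under LY. Of 32 macrophage maturation genes 0 passed over all genes (10 lower and 1 higher at an unadjusted p under 0.05) and 6 fell adjusted over the list alone, with a median of −1.01 (camera, adjusted p = 2.5e-08, and adjusted p = 0.42 with an estimated correlation). The median was −0.53 without HCMV replicate 2 and −0.52 without LY-pretreated replicate 1. Of 28 matrix and proteolysis genes 0 passed (8 lower and 2 higher at an unadjusted p under 0.05) and 3 fell adjusted over the list alone, with a median of −0.64 (adjusted p = 4e-04, and adjusted p = 0.42 with an estimated correlation). The cysteine protease gene CTSL differed by log2 −4.15 ± 0.55 (adjusted p = 0.053), SPP1, which encodes osteopontin, by −4.84 ± 0.79 (adjusted p = 0.132) and the lysosomal protease gene CTSD by −2.56 ± 0.55 (adjusted p = 0.23). Each of these genes belongs to both lists, so the maturation and matrix shifts are not separate results. The matrix median was −0.36 without HCMV replicate 2, −0.38 without LY-pretreated replicate 1, −1.02 without LY-pretreated replicate 2 and −1.32 with the filter at the 60th percentile. Of 30 M2-associated genes 1 fell, IL1RN, and 6 fell adjusted over the list alone, with a median of −0.235 (adjusted p = 0.0033, and adjusted p = 0.69 with an estimated correlation). The haemoglobin scavenger receptor gene CD163 differed by −3.62 ± 0.52 (adjusted p = 0.084), the mannose receptor gene MRC1 by −3.52 ± 0.90 (adjusted p = 0.338) and the transglutaminase gene TGM2 by −2.24 ± 0.37 (adjusted p = 0.139). The M2 median turned to 0.47 without HCMV replicate 2 (adjusted p = 0.62) and 0.06 without LY-pretreated replicate 1 (adjusted p = 0.075), and was −0.80 without HCMV replicate 1, −0.55 without LY-pretreated replicate 2 and −1.13 with the filter at the 60th percentile.

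Anti-apoptotic genes had a median of −0.14 over 16 genes and pro-apoptotic genes −0.17 over 24, and camera called neither (adjusted p = 0.32 and 0.14). MCL1 differed by −0.27 (95% interval −1.17 to 0.64), BCL2A1 by −1.14 ± 0.81 (adjusted p = 0.601), and ICAM1, an adhesion receptor gene, by −0.92 ± 0.42 (adjusted p = 0.537). Heat shock genes had a median of −0.48 over 11 genes (adjusted p = 0.0031, and adjusted p = 0.62 with an estimated correlation), with HSPB1 at −2.49 ± 0.55 (adjusted p = 0.24). The heat shock median ranged from −0.83 (without HCMV replicate 2) to −0.09 over the alternatives, and its call was not kept in all of them. Unfolded protein response genes had a median of −0.18 (adjusted p = 0.01, and adjusted p = 0.69 with an estimated correlation), which turned to 0.07 without HCMV replicate 1 (adjusted p = 0.19) and was −0.66 without HCMV replicate 2. Of 25 PI3K pathway genes 0 passed (4 higher at an unadjusted p under 0.05), with a median of 0.34 (camera, adjusted p = 0.16). The transcription factor genes FOXO1 and FOXO3, whose products AKT holds out of the nucleus, differed by 1.61 ± 0.45 (adjusted p = 0.408) and 1.06 ± 0.35 (adjusted p = 0.478). Among 18 FOXO target genes, whose median was 0.13 (adjusted p = 0.62), the insulin receptor substrate gene IRS2 differed by 1.63 ± 0.48 (adjusted p = 0.426).

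Camera called 14 of 30 lists in this comparison, 2 upwards and 12 downwards, against 0 with an estimated correlation and 0 in fry (lowest adjusted p = 0.12), and fry's mixed test, which sets direction aside, called 6. These were M2-associated (adjusted p = 0.00058), cytokine (0.0024), PI3K pathway (0.0087), matrix (0.014), maturation (0.014) and anti-apoptotic genes (0.034). The count of lists was 9 after quantile normalization and 9 with the filter at the 60th percentile. Lists with medians near 0 included oxidative phosphorylation (−0.24, adjusted p = 0.0028, and adjusted p = 0.73 with an estimated correlation), antigen presentation (−0.25, adjusted p = 0.021, and adjusted p = 0.73 with an estimated correlation) and pattern recognition genes (−0.08, adjusted p = 0.03, and adjusted p = 0.69 with an estimated correlation). Without LY-pretreated replicate 1 the oxidative phosphorylation median turned to 0.14 (adjusted p = 0.86) and that of antigen presentation was −1.14, and the pattern recognition call was lost (median −0.18, adjusted p = 0.06). Without LY-pretreated replicate 2 antigen presentation turned to 0.28 (adjusted p = 0.53), and pattern recognition was lost (adjusted p = 0.092), as it was without HCMV replicate 2 (median −0.0063, adjusted p = 0.29). Antigen presentation was also lost without HCMV replicate 1 (adjusted p = 0.098). The oxidative phosphorylation median was −0.12 without HCMV replicate 2 and −0.60 without LY-pretreated replicate 2, and that of pattern recognition −0.22 without HCMV replicate 1. LY96, a partner of the lipopolysaccharide receptor, differed by log2 −2.05 ± 0.39 (adjusted p = 0.197).

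Camera called 2 lists of markers of other cells in this comparison. Of 14 T cell and 10 NK cell markers 0 passed over all genes in limma (1 higher and 1 lower at an unadjusted p under 0.05) and 0 adjusted over the list alone. T cell markers had a median of 0.86 (camera, adjusted p = 0.03) and ribosomal protein genes of 0.48 (adjusted p = 0.03), with adjusted p = 0.73 and adjusted p = 0.75 with an estimated correlation. NK cell markers had a median of −0.55 over 10 genes (adjusted p = 0.021, and adjusted p = 0.73 with an estimated correlation). The granzyme gene GZMB, expressed by cytotoxic cells, had a log2 signal of 9.07 ± 1.40 under LY and 13.61 ± 3.23 in HCMV (adjusted p = 0.471). The NK median turned to 0.57 without HCMV replicate 1 (adjusted p = 0.33) and 0.18 without LY-pretreated replicate 2 (adjusted p = 0.48), and was −2.38 without HCMV replicate 2 and −1.52 without LY-pretreated replicate 1. The T cell call was lost without HCMV replicate 2 (median 0.54, adjusted p = 0.8) and LY-pretreated replicate 1 (median 0.49, adjusted p = 0.23), and was 1.39 without HCMV replicate 1. The ribosomal call was lost without HCMV replicate 2 (median 0.21, adjusted p = 0.63) and LY-pretreated replicate 2 (median 0.29, adjusted p = 0.66), and the median was 0.74 without HCMV replicate 1. The median of all probe sets tested was 0.24 here, and 0.08 after quantile normalization.

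The genes that infection raised were set against those that LY lowered. Of the 4 probe sets raised by infection, 3 were lowered by LY (CCL7, CCL8 and IFI27) and 0 were raised further, while IL6 stayed at 15.22 ± 0.22. Independent lists of these sizes would share 0.00478 probe sets in this direction, and simulated unchanged groups that share the HCMV arrays gave 0.04. These simulations held no infection effect. They therefore do not give the overlap that the shared arrays alone produce among probe sets raised by infection. The HCMV group cannot be split into parts of 2 arrays, so part of the overlap may come from the shared arrays. Across probe sets the 2 sets of log2 differences correlated with r = −0.551, against −0.499 in the simulations, and their covariance was −0.402 against −0.172. The differences of HCMV and of LY from mock, which share the mock arrays, correlated with r = 0.482, against 0.5 in the simulations. Their covariance was 0.335 against 0.173. The covariances thus exceeded the simulated ones both towards a shift back and towards a change kept. The count of probe sets raised by infection and lowered by LY was 0 without either mock array or without LY-pretreated replicate 2, 1 without HCMV replicate 1, 5 without HCMV replicate 2, 6 without LY-pretreated replicate 1 and 1 without the intensity trend.

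The size of the infection response that remained under LY was measured on arrays not used to choose the genes. Probe sets that were at least 2-fold higher in HCMV in 1 replicate number kept 21.1% ± 2.75 (SD of the 2 directions of the split, with no test) of their infection difference under LY in the other. In the direction chosen on replicate 1, 780 probe sets had a mean infection difference of log2 0.52 in replicate 2 and 0.10 under LY. In the other direction, 757 probe sets had 0.66 and 0.15. Both differences use the same mock array and so share its error. The median of all probe sets tested was itself 0.1 in LY against mock and −0.18 in HCMV against mock. No such offset was subtracted, so the small differences kept under LY cannot be told apart from one. The share was 12.2% after quantile normalization and 60.5% with no filter. For probe sets that were lower after infection the directions gave 63.7% and −136%, so no share could be set for them.

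LY-pretreated infected cells were compared with mock cells to show how far they lay from uninfected monocytes. IL6 and CCL20 rose and LIPA, the lysosomal acid lipase gene, fell. The count was 2 risen and 1 fallen (limma, adjusted p under 0.05), with 468 at an unadjusted p under 0.05. IL6 rose 222-fold (log2 7.8 ± 0.76), CCL20 rose 54.2-fold (log2 5.76 ± 0.54), from 8.32 ± 0.32 to 14.08 ± 0.14, and LIPA fell 26.4-fold (log2 −4.72 ± 0.46), from 16.64 ± 0.10 to 11.92 ± 0.74. Each had an adjusted p of 0.0327 and no overlap between groups. Over all alternatives the adjusted p ranged from 0.0077 to 0.28 for IL6 and LIPA and from 0.0064 to 0.28 for CCL20, and the log2 differences from 6.97 to 8.62, −5.24 to −4.2 and 5.39 to 5.99. The count was 0 without mock replicate 1 (424 at an unadjusted p under 0.05), mock replicate 2 (241) or LY-pretreated replicate 1 (438), where the 3 genes had adjusted p of 0.2, 0.28 and 0.18. It was 1 without LY-pretreated replicate 2, where they had 0.067 to 0.095, 13 without HCMV replicate 1 and 11 without HCMV replicate 2. The count was 0 after quantile normalization (517 at an unadjusted p under 0.05) and 0 without the intensity trend (464), 7 with no filter, 12 with only the groups compared, and 20 without both first infected arrays, a setting chosen after the data were seen.

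Inflammatory cytokines had a median above 0 against mock under LY, while the interferon-stimulated list was not called. The difference between the 2 lists was not tested. Of 31 cytokines and NF-kB targets, 2 rose over all genes and 16 adjusted over the list alone, with a median of 1.67 (camera, adjusted p = 3.6e-17, and adjusted p = 0.38 with an estimated correlation). That median was 0.97 without mock replicate 2 and 1.02 without LY-pretreated replicate 1. IL1B differed by log2 5.37 ± 0.65 (adjusted p = 0.0731), the chemokine gene CCL3 by 3.14 ± 0.49 (adjusted p = 0.104) and TNF by 2.07 ± 0.72 (adjusted p = 0.63). The interferon list had a median of −0.04 over 39 genes, with 2 lower adjusted over the list alone and 0 over all genes (3 lower at an unadjusted p under 0.05), and camera did not call it (adjusted p = 0.16). The median was 0.045 after quantile normalization, 0.73 without LY-pretreated replicate 2 and −1.19 without LY-pretreated replicate 1. Its direction thus depended on which LY-pretreated array was kept, and the median near 0 does not show a return to mock levels. LGALS3BP differed by −2.87 ± 0.40 (adjusted p = 0.0988) and IFITM3 by −3.13 ± 0.63 (adjusted p = 0.245). M1-associated genes had 2 risen and 4 adjusted over the list alone (median 1.3, adjusted p = 1.8e-05, and adjusted p = 0.84 with an estimated correlation), a call lost without LY-pretreated replicate 1 (median 0.07, adjusted p = 0.56). Its median was 2.25 without LY-pretreated replicate 2. The 2 M1-associated genes that rose were IL6 and CCL20, which also belong to the cytokine list.

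Macrophage maturation, M2-associated and matrix genes had medians below 0 against mock in the LY-pretreated cells. Of 32 macrophage maturation genes 1 fell over all genes, LIPA, and 13 fell adjusted over the list alone. Without overlap 24 lay lower, where chance gives 16.7% for a single gene. The median was −1.46 (camera, adjusted p = 4.2e-19, and adjusted p = 0.25 with an estimated correlation), and −0.94 without LY-pretreated replicate 1. GPNMB differed by log2 −7.66 ± 0.91 (adjusted p = 0.073) and FABP4 by −6.86 ± 1.05 (adjusted p = 0.104). Of 30 M2-associated genes 1 fell, LIPA, 7 fell adjusted over the list alone, and 16 lay lower and 3 higher without overlap, with a median of −0.73 (adjusted p = 2e-08, and adjusted p = 0.42 with an estimated correlation). CD163 differed by −3.73 ± 0.52 (adjusted p = 0.0988), CLEC10A by −3.29 ± 0.61 (adjusted p = 0.202), IL1RN by −3.86 ± 0.74 (adjusted p = 0.215) and MRC1 by −3.5 ± 0.90 (adjusted p = 0.415). The M2 median was −1.11 without mock replicate 2 and −1.36 without LY-pretreated replicate 2. Of 28 matrix and proteolysis genes 0 passed (10 lower and 1 higher at an unadjusted p under 0.05), 2 fell adjusted over the list alone, and 12 lay lower and 5 higher without overlap, with a median of −0.81 (adjusted p = 0.00074, and adjusted p = 0.37 with an estimated correlation), and −1.37 with the filter at the 60th percentile. CTSD differed by −3.67 ± 0.55 (adjusted p = 0.104).

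Classical monocyte genes had a median of −1.72 over 16 genes, with 2 lower adjusted over the list alone and 0 over all genes (5 lower at an unadjusted p under 0.05; camera, adjusted p = 1e-05, and adjusted p = 0.74 with an estimated correlation). RNASE6, a gene for an antimicrobial ribonuclease, differed by log2 −4.67 ± 0.84 (adjusted p = 0.179) and the nuclear antigen gene MNDA by −2.27 ± 0.59 (adjusted p = 0.419). The list mean lay at −1.93 on LY-pretreated replicate 1, on which 18S ribosomal RNA probe sets read 38720, and at 0.59 on replicate 2, on which they read 1446. Without LY-pretreated replicate 1 the call was lost (median −0.38, adjusted p = 0.48), and without replicate 2 the median was −3.05. Oxidative phosphorylation genes had a median of −0.47 (adjusted p = 0.00022, and adjusted p = 0.84 with an estimated correlation) and lost their call without LY-pretreated replicate 1 (median −0.04, adjusted p = 0.77), with −0.78 without replicate 2.

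Anti-apoptotic genes had a median of 0.32 over 16 genes (adjusted p = 0.028) and cell cycle genes of 0.35 over 21 (adjusted p = 0.029), each with adjusted p = 0.84 with an estimated correlation. The kinase gene PIM1 differed by log2 2.24 ± 0.52 (adjusted p = 0.344), CFLAR by 1.73 ± 0.39 (adjusted p = 0.309), BCL2A1 by 1.22 ± 0.81 (adjusted p = 0.896) and MCL1 by 0.37 (95% interval −0.535 to 1.28, adjusted p = 0.936). Both calls were lost without LY-pretreated replicate 1 (adjusted p = 0.15 for each) and without replicate 2 (anti-apoptotic median 0.7, adjusted p = 0.061, cell cycle median 0.53, adjusted p = 0.084). The anti-apoptotic call was also lost without mock replicate 2 (adjusted p = 0.086) and the cell cycle call without mock replicate 1 (adjusted p = 0.18).

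Camera called the lymphocyte marker lists downwards against mock. Of 10 NK, 7 B and 14 T cell markers 0 passed over all genes in limma (0, 3 and 1 lower at an unadjusted p under 0.05), and 0, 2 and 0 fell adjusted over the list alone. The medians were −1.33 for NK cells (camera, adjusted p = 0.00088, and adjusted p = 0.84 with an estimated correlation), −1.39 for B cells (adjusted p = 0.00056, and adjusted p = 0.74 with an estimated correlation) and −0.585 for T cells (adjusted p = 0.016, and adjusted p = 0.84 with an estimated correlation). The immunoglobulin gene IGHM differed by log2 −1.81 ± 0.43 (adjusted p = 0.356) and the B cell surface gene MS4A1 by −1.66 ± 0.63 (adjusted p = 0.737). The T cell call was lost without mock replicate 2 (median −0.10, adjusted p = 0.96) and LY-pretreated replicate 2 (median −0.20, adjusted p = 0.36), and was −1.06 without mock replicate 1. The NK call was lost without LY-pretreated replicate 2 (adjusted p = 0.21). The B cell median was −0.415 without mock replicate 2 and −0.85 without LY-pretreated replicate 1.

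**Figure D2:**
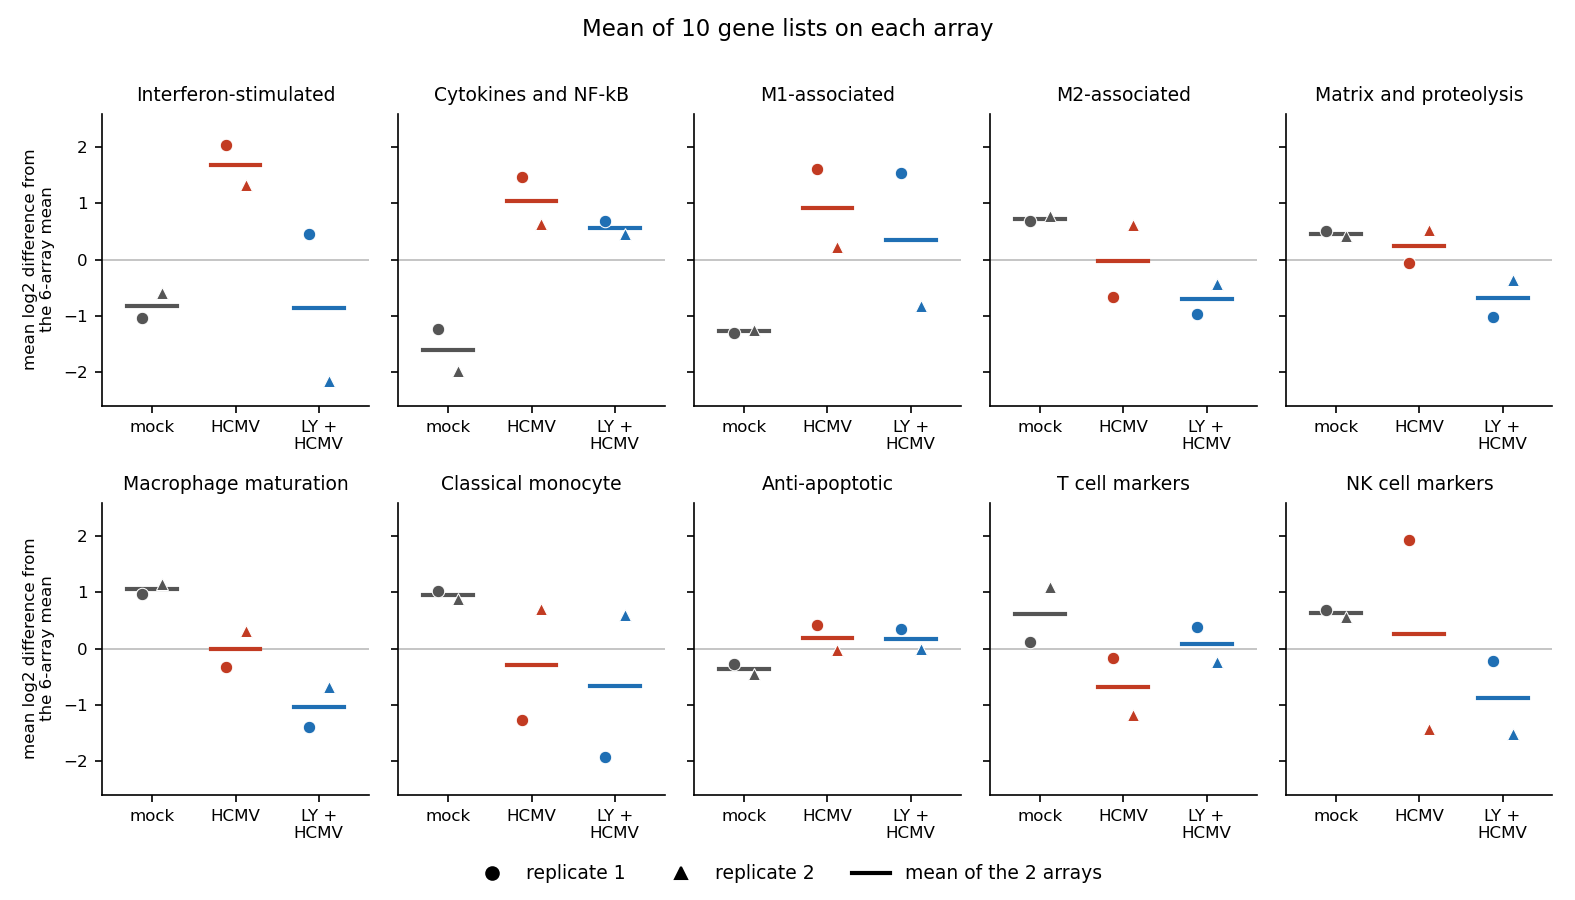
Mean log2 difference from the 6-array mean (vertical axis, log2 units) of 10 gene lists on each array of the mock, HCMV and LY-pretreated HCMV groups, with circles for replicate 1, triangles for replicate 2, bars for the mean of the 2 arrays and a grey line at 0. Cytokine means lay at 0.69 and 0.45 on the LY-pretreated arrays and interferon-stimulated gene means at 0.45 and −2.17, and classical monocyte genes lay low on the first array of both infected groups.

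The remaining lists were not called by camera in any comparison. Medians in HCMV against mock, LY against HCMV and LY against mock were −0.24, 0.07 and −0.03 for adhesion and motility genes, and −0.05, −0.07 and −0.11 for cholesterol and fatty acid synthesis genes. They were −0.07, −0.19 and −0.14 for glycolysis and hypoxia genes and 0.26, 0.05 and 0.42 for metallothionein and oxidative stress genes. FOXO targets and PI3K pathway genes had −0.31 and −0.30 in HCMV against mock, and 0.45 and 0.19 in LY against mock. Among markers of other cells they were −0.75, 1 and 0.23 for platelets, −0.56, 0.64 and −0.35 for neutrophils, and −0.115, 0.57 and 0.19 for erythroid cells. Fibroblast markers had 0.07, 0.26 and −0.03, and dendritic cell markers had 0.515, −0.01 and 1.03. The dendritic list mean differed between replicates 1 and 2, at 0.81 and −0.33 in HCMV and 1.11 and −0.97 under LY. In mock it lay at −0.27 and −0.35. Quantile normalization changed the sign of the cholesterol, glycolysis and erythroid medians in HCMV against mock and of the fibroblast and dendritic cell medians in LY against HCMV. In LY against mock camera called 12 lists, 4 upwards and 8 downwards, against 0 with an estimated correlation and 0 in fry (lowest adjusted p = 0.096), and fry's mixed test called 3, those of cytokine, M1-associated and maturation genes (each adjusted p = 0.037). As a limit on all list calls, a comparison of replicate 1 with replicate 2 over the 3 groups, in which no treatment differs, called 14 of 30 lists by camera and 0 probe sets (591 at an unadjusted p under 0.05).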

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

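The tests of degraded RNA and of ribosomal RNA were chosen after the result was seen, and the test of the share of myeloid cells before it. Control probe sets, which stayed in the scaling and out of the tests, read high on the first array of the infected groups. Those for 18S and 28S ribosomal RNA and the hybridization spikes lay above both mock arrays there. The Alu control did not on HCMV replicate 1, at 236800 against 272800 on mock replicate 2. The 28S controls also lay above both mock arrays on LY-pretreated replicate 2 (5465). The 18S ribosomal RNA controls read 29940 on HCMV replicate 1 and 38720 on LY-pretreated replicate 1, against 12320 on the higher mock array (2.43-fold and 3.14-fold). They were higher on replicate 1 than on replicate 2 in every group, at 12320 against 657.2 in mock. In HCMV the readings were 29940 against 110.6 and under LY 38720 against 1446. Whether this goes with a source shared by replicate number was not tested. On LY-pretreated replicate 1 the 28S controls read 12970 against 4687 (2.77-fold), and the hybridization spikes, which are added in fixed amount before hybridization, read 19930 against 9779 (2.04-fold). With 2 mock arrays, the range of such signals in mock is poorly known.

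Classical monocyte genes were lower on these same arrays, by a median log2 difference between replicates 1 and 2 of −1.44 in HCMV and −2.25 in LY-pretreated cells, over 16 genes. Degraded RNA and ribosomal RNA in the labelled sample stay open: the ratio of 3' to 5' signal of ACTB was higher on the low array in both infected groups (1.54 against 1.05 in HCMV and 1.44 against 1.12 under LY, at least 1.29 times), but reached 2.78 on mock replicate 2. The same ratio of GAPDH was 1.12 against 1.04 in HCMV but ran the other way under LY, at 0.935 against 1.2. It was also highest on mock replicate 2 (1.6), where the monocyte list mean was 0.884. Mock replicate 1, with an 18S signal of 12320 against 657.2, differed from mock replicate 2 by a median of −0.0482 (median absolute deviation 0.493), and both signals lay below those of the arrays at issue. A lower share of myeloid cells may also account for part of the pattern and cannot be told apart from a change within the monocytes: 21 other myeloid genes differed by a median of −0.583 in HCMV (median absolute deviation 0.801) and −0.485 in LY-pretreated cells (0.661), a spread wider than the difference. The labels give no difference between the replicates of a group, so no explanation by the design was tested.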

How the results depend on the processing

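The alternative without both first infected arrays was chosen after the data were seen, and the others were planned. In HCMV against mock, 4 probe sets became 1 without the intensity trend, 9 with only the groups compared and 13 with the replicate number as a block, and 5 with quantile normalization. In LY against HCMV, 9 became 17 with no filter, 17 with the block and 7 with quantile normalization. In LY against mock, 3 became 0 with quantile normalization and 0 without the intensity trend in limma (517 and 464 at an unadjusted p under 0.05), 7 with no filter, 12 with only the groups compared, 31 with the block and 20 without both first infected arrays. Leaving out 1 array gave 0 (without mock replicate 1 or 2) to 13 (without HCMV replicate 2), 3 (without HCMV replicate 1 or LY-pretreated replicate 2) to 18 (without LY-pretreated replicate 1), and 0 (without mock replicate 1 or 2 or LY-pretreated replicate 1) to 13 (without HCMV replicate 1). The 3 probe sets shifted back by LY became 1 without the intensity trend, and 0 (without mock replicate 1) to 6 (without LY-pretreated replicate 1). With no filter more dim probe sets are tested, and with an array less or only the groups compared the spread rests on fewer arrays. The cause of the other changes was not tested. Replicate numbers are not known to pair the samples: across probe sets the replicate differences correlated with r = 0.459 between HCMV and LY-pretreated cells and with −0.0668 and −0.0612 between mock and these.

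The share of the infection effect kept under LY for raised probe sets moved from 21.1% to 12.2% with quantile normalization and 60.5% with no filter. With no filter that of lowered probe sets moved from −36.2% to −989% and that of both from 0.554% to −89.3%. For lowered probe sets the share was 50.8% with quantile normalization and 28.7% with the filter at the 60th percentile. For both it was 23.8% and 23.1%. The main share of lowered probe sets averages 63.7% and −136% (SD 141), so it sets no usable level. The cause was not tested. It was not recomputed for single arrays, since its split uses each array.

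Camera called 12, 14 and 12 lists in the 3 comparisons. With an estimated correlation 0, 0 and 0 were called and with fry 0, 0 and 0, while in LY against HCMV 9 were called with quantile normalization and 9 with the filter at the 60th percentile. Over the settings with the preset correlation, interferon-stimulated, cytokine, M1-associated, anti-apoptotic and T cell genes kept their call in HCMV against mock. Interferon-stimulated, matrix and maturation genes did so in LY against HCMV, and cytokine, M2-associated, matrix, maturation and B cell genes in LY against mock. For the other called lists the highest adjusted p lay between 0.14 and 0.91, 0.091 and 0.98, and 0.15 and 0.96.

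Lists that changed direction where they were called in either setting are given here, and lists called in neither are left out. In HCMV against mock, cell cycle genes (0.398) ranged from −0.204 to 1.1 when 1 array was left out, NK cell markers (−0.47) from −1.74 to 0.95, and glycolysis genes (−0.0691) from −0.158 to 0.0733. In LY against HCMV the ranges were −0.381 to 0.377 for cytokines, −1.2 to 0.283 for M1-associated genes, −0.796 to 0.467 for M2-associated genes, −0.332 to 0.324 for adhesion genes and −0.657 to 0.0661 for unfolded protein response genes. They were −1.14 to 0.283 for antigen presentation, −0.596 to 0.143 for oxidative phosphorylation and −2.38 to 0.572 for NK cell markers. In LY against mock they were −0.669 to 0.399 for antigen presentation (0.182) and −1.19 to 0.728 for interferon-stimulated genes. Without both first infected arrays the medians were −0.204 for cell cycle and 0.0733 for glycolysis genes in HCMV against mock, 0.138 for cytokines, 0.0165 for oxidative phosphorylation and 0.0293 for NK cell markers in LY against HCMV, and −0.669 for antigen presentation in LY against mock. With the filter at the 60th percentile pattern recognition genes in LY against HCMV moved from −0.0761 to 0.0128. The cause was not tested.

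Of the other values, those of the named genes stayed on their side of the threshold in 3919 cases, crossed it upwards in 65 and downwards in 57, and changed direction in 0 where either value passed. In 107 of the 3919 the direction changed while neither passed, such as IL6 in LY against HCMV (−1 to 1.14 over the alternatives). Lists stayed in 1427 cases, of which 145 changed direction uncalled, crossed in 28 and 141, and changed direction in 24 where either setting called them. Signals near the background of these arrays limit what can be said of dim genes.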

Other observations

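The tests of interferon gamma, of lymphocytes and NK cells and of the first LY-pretreated array were chosen after the result was seen, and those of an exchanged sample and of scaling before it. The genes in this part were chosen after their values were seen, except those that the rule for named genes takes. Among neutrophil-attracting chemokine genes, CXCL1 differed from mock by log2 5.58 ± 0.86 in HCMV and 4.82 ± 0.86 under LY, CXCL3 by 4.52 ± 0.71 and 4.44 ± 0.71, CXCL5 by 5.95 ± 1.32 and 5.1 ± 1.32, and CXCL8 by 4.37 ± 1.13 and 4.74 ± 1.13. The lowest adjusted p among these in limma was 0.11, so none passed. Between LY and HCMV the 95% interval was −2.28 to 3.03 for CXCL8 and −1.73 to 1.58 for CXCL3, and the sign of both differences changed after quantile normalization (−0.12 and 0.12). The monocyte-attracting chemokine genes CCL7 and CCL8 differed from mock by log2 0.62 and −0.31 under LY. CCL2, of the same kind, read 9.24 and 14.16 on the LY-pretreated arrays, against 17.47 and 16.97 in HCMV. Whether these genes differed from the others in their response to LY was not tested.

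The chemokine genes that interferon gamma induces differed widely between replicates. CXCL9 read 17.06 and 8.73 on the LY-pretreated arrays and 14.05 and 6.20 in HCMV, CXCL10 16.22 and 6.07 against 16.12 and 13.04, and CXCL11 15.94 and 5.77 against 14.82 and 9.21. SELENOP, a selenium transport gene of macrophages, differed between HCMV and mock by log2 −6.79 ± 0.84 (adjusted p = 0.0836) and lay at −4.55 ± 0.84 under LY (adjusted p = 0.202). MXI1 and RGS2, a MYC antagonist and a regulator of G protein signalling, differed between HCMV and mock by −1.54 ± 0.35 (adjusted p = 0.323) and −1.98 ± 0.42 (adjusted p = 0.284) and between LY and HCMV by 2.31 ± 0.35 (adjusted p = 0.102) and 2.65 ± 0.42 (adjusted p = 0.111), without overlap of the arrays.

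All 39 interferon-stimulated genes read higher on LY-pretreated replicate 1 than on replicate 2, with a mean difference of 2.61. An exchange of the first LY-pretreated sample for an HCMV sample is argued against by 34 genes that were at least 8-fold lower under LY on the second arrays: they were also lower on the first, by a median of −2.84 (median absolute deviation 1.49). Quantile normalization left the difference at 2.66, which argues against scaling of whole arrays only weakly, since the arrays already shared a trimmed mean. An interferon gamma response in replicate 1 may contribute and cannot be told apart from other differences between the samples: 18 interferon gamma genes differed by a median of 0.989 in HCMV, 2.49 under LY and 0.59 in mock, while 19 type I interferon genes differed by 0.61, 2.18 and −0.92. Between LY and HCMV the type I genes differed by −2.98 in replicate 1 and −5.07 in replicate 2, and the interferon gamma genes by 0.32 and −1.13.

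Macrophage maturation genes had a median of −1.46 against mock under LY. Together, 31 T, NK and B cell markers differed from mock by a median of −0.77 (median absolute deviation 0.437 over genes that move together). More NK and B cells among the LY-pretreated cells is argued against, since both LY-pretreated arrays lay below both mock arrays. The list means were −0.224 and −1.53 against 0.688 and 0.568 for NK cells. For B cells they were −0.617 and −0.355 against 0.0588 and 1.03. T cell means overlapped (0.376 and −0.232 against 0.115 and 1.1), so for T cells the test cannot decide. A contribution from the first LY-pretreated array, on which the list mean was −1.4 against −0.69 on the second, cannot be told apart from an effect of LY: on the second array alone the median was −0.94 (median absolute deviation 1.03, 32 genes). LY and infection may each contribute, and since no cells received LY without virus, their effects on these genes stay open.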
